A study of Mus musculus with 2 samples.

How the data were processed

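Total RNA of mouse embryonic stem (ES) cells was measured on 2 Affymetrix arrays, 1 for cells given a control hairpin and 1 for cells given a hairpin against Tet2. Per the labels' protocols, lentivirus delivered the hairpins, cells were kept in puromycin for 72 hours, and 2 µg of RNA per sample was copied from a T7-oligo(dT) primer into biotin-labelled cRNA. Probe set names carry the mark of a design with perfect-match probes alone.

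The values used are the authors' deposited table of log2 signal per probe set, made with Affymetrix Expression Console per the submitters' processing notes. The program's version, the summary method, the background correction and the normalization are not given in the sources used here. The log base is also unstated and was read from the values. As natural logarithms, the maximum of the array labelled control KD would be 95197.5 on the linear scale, above the 65535 that a 16-bit scanner can record, so the values were taken as log2. The array labelled control KD had a median of 2.57 and a maximum of 11.46, and the array labelled TET2 KD a median of 2.55 and a maximum of 14.10. Scanner files were not used here.

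The table has 45141 probe sets, of which 104 are Affymetrix controls. Of the other 45037, the platform annotation gives 1 gene symbol for 28898, several for 551 and none for 15588. Only probe sets with 1 symbol were given a gene name. Symbols of the gene lists were matched through the annotation and through a RefSeq gene table of assembly GRCm38.p6, used for names alone, and 805 of 978 list entries fixed beforehand found a probe set. The annotation names no Tet1 probe set.

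The following choices were made before the data were examined. A gene was represented by the probe set with the highest mean of both arrays. The floor was the median of all values of probe sets other than controls, 2.55 on the log2 scale, and 11174 of 17098 genes had a mean at or above it. Differences are the array labelled TET2 KD minus the array labelled control KD on the log2 scale, and a gene was counted as higher or lower at 2-fold, a log2 difference of 1. Where a gene was under the floor on 1 array, its call rests on the difference as measured, and its fold is given as a bound against the floor. Each of 33 gene lists with at least 5 members at or above the floor was described by its median difference and by the percentile of that median among 10000 random lists of the same size, drawn from the same 20 bins of mean level. A list stood apart outside the central 95% of random medians. That percentile describes these 2 arrays and is no test of the conditions.

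The genes named were set by rule. They are Tet1, Tet2, Tet3, Ogt, Pou5f1, Sox2 and Nanog; the 10 with the largest positive and the 10 with the largest negative differences among genes at or above the floor on both arrays, provided that their other probe sets at or above the floor had the same sign; the 5 with the largest bounds in each direction among genes under the floor on 1 array; and up to 4 members of each list with the largest differences. Genes with clone or model names were passed over, which left out 3 past 2-fold, and 26 genes past 2-fold were set aside because another probe set had the other sign. Genes named to show levels on both arrays, and list members beyond those 4, were chosen after their values were seen.

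After the values were seen, 5 further lists were written, for neurons, oligodendrocytes, astrocytes, the pituitary, and olfactory and airway epithelium. Second lists for the pituitary, for olfactory and airway epithelium, and for proliferation were written later still, before the values of their members were looked at. Alternatives covered the scaling of the arrays, the floor, the rule for several probe sets, the 2-fold threshold and the way lists were summarised.

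The procedures were tested on simulated data with the spread of these arrays for the 11174 genes. All of 100 genes set 4-fold apart and 96% of 100 genes set 2.378-fold apart passed 2-fold, and 0 of 10974 unchanged genes did. Of 50 lists with no shift, 6% fell outside the central range, and 92% of lists shifted by 0.15 did. The simulated noise was normal with the robust SD of these differences, so it holds no probe set errors of other kinds. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

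A total of 1892 probe sets share both of their values, to all 9 decimals, with at least 1 other probe set. They form 859 groups, 554 of them at or above the floor, and 375 of those join probe sets of different named genes. Their share was 3.46% under the floor and 6.27% at a mean level of 6 and over. In a separate count, 610 probe sets had the same value on both arrays. How these equal values arose is not known, and whether values and probe set names are aligned throughout the table could not be checked without the scanner files.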

Results

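Gene expression was compared between 2 arrays, labelled as mouse ES cells with a control hairpin and with a hairpin against Tet2, a dioxygenase that oxidises 5-methylcytosine in DNA. ES cells are pluripotent cells of the early embryo, and puromycin selects those carrying the virus. There was 1 array per group and no replicate, so every difference below lacks an error and a test of the conditions, and the number of arrays limits the precision. Each value is given under the gene name that the annotation pairs with its probe set, and whether values and names are aligned throughout could not be checked without the scanner files.

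The targeted gene was read first, since it checks the labels. Tet2 was measured by 2 probe sets, and neither was 2-fold lower in the array labelled TET2 KD. The dimmer one read 5.48 in the array labelled control KD and 5.22 in the array labelled TET2 KD, a difference of -0.26, or 83.7% of the control level. The brighter one read 5.62 and 5.57, a difference of -0.06, or 96.2% of the control level. Where these probe sets lie on the transcript, and so how well they read the knockdown, is not known here. Tet3, a related dioxygenase, read 3.15 and 3.36. The 4 probe sets of Ogt, the O-GlcNAc transferase that binds TET proteins, differed by -0.05 to 0.25. Because Tet2 did not separate the arrays as labelled, the samples are called the array labelled control KD and the array labelled TET2 KD throughout, and no direction below can be assigned to a loss of Tet2.

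Marker genes of ES cells lay both high and at background on both arrays. Of 34 pluripotency genes measured, 21 (61.8%) were at or above the floor on both arrays and 12 were under it on both, beside 63.96% of all genes at or above it. Zfp42, a marker of undifferentiated ES cells, read 10.56 and 10.58, Utf1 9.22 and 9.22, Sall4 8.73 and 8.75, and Dppa4 8.64 and 8.45. Sox2 read 7.09 and 6.98. Pou5f1 and Nanog, core transcription factors of pluripotency, read 1.07 and 1.29, and 1.01 and 0.97, all under the floor of 2.55. Each of these 2 factors has 1 probe set in the annotation.

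Several genes of brain cells were at high levels on both arrays, and others lay near or under the floor. Of 13 oligodendrocyte genes, 12 (92.3%) were at or above the floor on both arrays, among them Mbp, a myelin protein, at 10.32 and 10.22. Of 19 neuronal genes 16 were, with Stmn2 at 10.34 and 10.35, although Snap25, a synaptic vesicle fusion protein, read 2.51 and 2.26. Of 10 astrocyte genes 8 were, with the water channel Aqp4 at 8.49 and 8.33. Mog, another myelin protein, read 3.32 and 3.18. These 3 lists were chosen after the values had been seen. Their median differences, -0.08 for oligodendrocytes, 0.01 for neurons and -0.0025 for astrocytes, lay within the range of random lists, and 1 of their members, Opalin, an oligodendrocyte membrane protein, was past 2-fold (1.13, or 0.40 in the mean of its probe sets). In the cell cycle list, Ccna2, a cyclin, read 8.75 and 8.86 and Plk1, a mitotic kinase, 8.13 and 8.09. Mki67, the Ki-67 antigen, read 1.08 and 0.97, and Cdk1, the main mitotic kinase, 2.14 and 1.96.

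**Figure D1:**
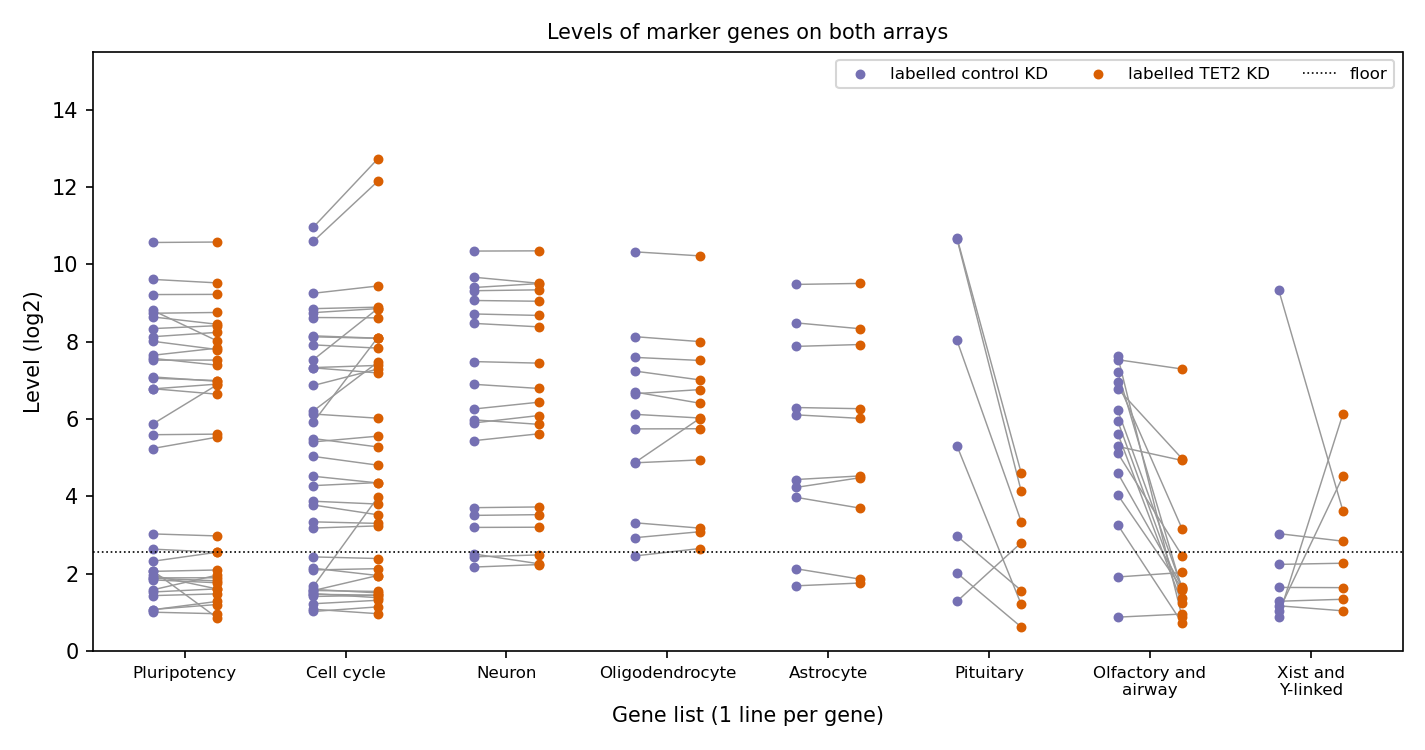
Levels of marker genes (log2, vertical axis) by gene list (horizontal axis), with a line for each gene joining the array labelled control KD to the array labelled TET2 KD and the floor of 2.55 dotted. Pluripotency and cell cycle genes lie both well above and under the floor on both arrays, while Prl, at 10.66 and 4.13, and Xist, at 9.34 and 3.62, differ between the arrays.

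Xist and 2 of 7 Y-linked genes differed between the arrays in opposite directions. Xist, the RNA that coats the inactive X chromosome of female cells, read 9.34 in the array labelled control KD and 3.62 in the array labelled TET2 KD, and its other 2 probe sets, under the floor in the array labelled TET2 KD, were at least 22.7-fold and 27.6-fold lower there. The Y-linked genes Eif2s3y and Kdm5d were under the floor in the array labelled control KD and read 6.14 and 4.52 in the array labelled TET2 KD, at least 12.0-fold and 3.91-fold higher. In the mean of their probe sets these differences were 3.13 and 1.19. Sry, the testis-determining gene of the Y chromosome, was at or above the floor on both arrays and did not separate them, at 3.04 and 2.84. The other 4, Uty, Usp9y, Zfy1 and Zfy2, were under the floor on both arrays. Ddx3y, a further Y-linked gene, found no probe set of its own in the annotation and is not among the 7.

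Pituitary hormone genes were far lower in the array labelled TET2 KD. Prl, prolactin, read 10.66 in the array labelled control KD and 4.13 in the array labelled TET2 KD, 92.5-fold apart. Gh, growth hormone, read 10.69 and 4.60, 68.1-fold apart, and differed by -6.83 without probe sets marked as shared between transcripts. Pomc, the precursor of corticotropin, read 8.04 and 3.35, 25.8-fold apart. All 4 members of a pituitary list at or above the floor were lower by 2-fold or more. Cga, the shared subunit of the glycoprotein hormones, went the other way, at 1.29 and 2.80.

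Genes of olfactory and airway epithelium were lower in the array labelled TET2 KD as well. Bpifa1, a protein secreted in the upper airway, was at least 33.5-fold lower, and the cytochromes Cyp2a5, Cyp2g1 and Cyp2f2 at least 25.4-fold, 12.8-fold and 8.41-fold lower. Stoml3, a stomatin of sensory neurons, was at least 10.5-fold lower, and Sec14l3 read 6.95 and 3.16. Of 12 members of a list for these epithelia at or above the floor, 10 were lower by 2-fold or more, with a median of at most -2.82 when values under the floor were set to it. Omp, a marker of olfactory neurons, was under the floor on both arrays, at 1.92 and 2.03. The pituitary and epithelial lists were written from genes already seen to differ, so their counts are no independent evidence.

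Across all genes the arrays were close. Of 11174 genes at or above the floor, 131 (1.17%) were higher by 2-fold or more in the array labelled TET2 KD and 158 (1.41%) were lower. With the floor at the 75th percentile the numbers were 80 and 60, the other way round, and at a threshold of 1.5-fold they were 199 and 606. On both arrays at or above the floor were 105 of the former and 108 of the latter. The median difference was -0.01, the robust SD 0.146, and 81.4% of genes differed by less than 0.25. Pearson's r across genes was 0.975, where genes are not independent replicates.

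**Figure D2:**
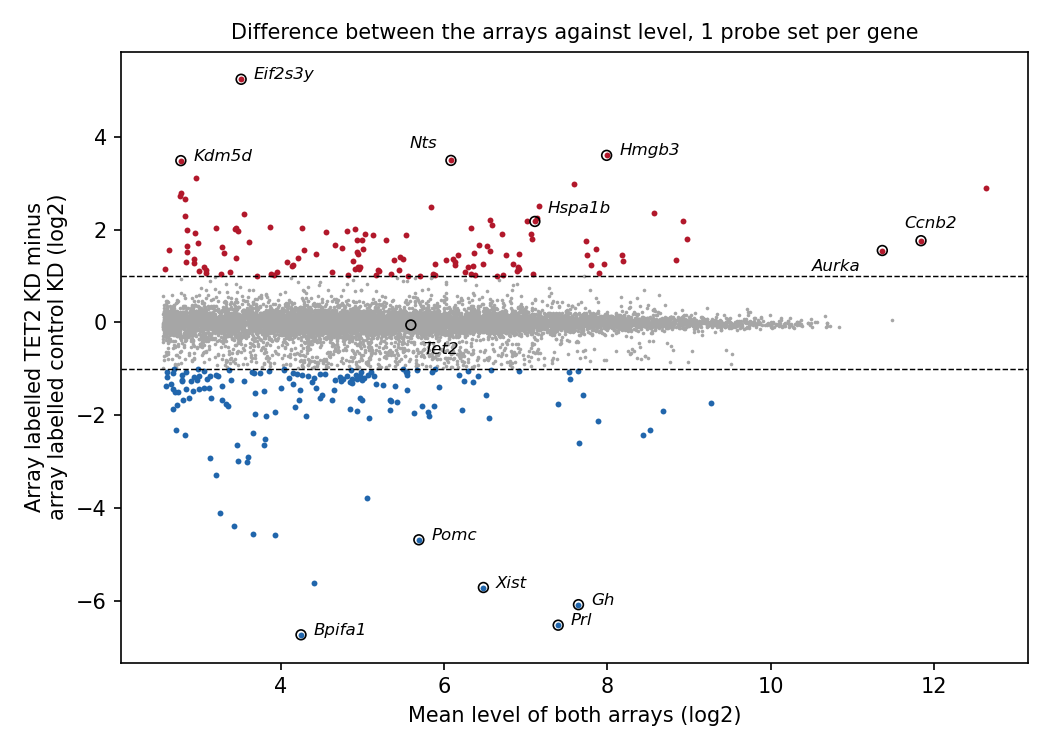
Difference between the arrays (array labelled TET2 KD minus array labelled control KD, log2, vertical axis) against the mean level of both arrays (log2, horizontal axis), 1 point per gene, with 2-fold as dashed lines, 131 genes higher in red and 158 lower in blue. Tet2, at -0.06, lies close to 0, and Prl, at -6.53, among the farthest.

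Among genes at or above the floor on both arrays, the largest difference upward was that of Hmgb3, a high mobility group chromatin protein, at 6.19 in the array labelled control KD and 9.79 in the array labelled TET2 KD, 12.2-fold apart. Nts, the neuropeptide neurotensin, followed at 4.34 and 7.83, and Adamts20, a secreted metalloprotease, at 6.10 and 9.09. Genes of cell division were Fam83d (difference 2.49), the phosphatase Cdkn3 (2.35) and the spindle factor Tpx2 (2.18). The others were Gas7 (2.51), the fibrinogen chain Fga (2.25), the ciliary neurotrophic factor receptor Cntfr (2.22) and Hspa1b, an inducible heat shock protein (2.18). In the mean of their probe sets Cntfr differed by 1.19 and Tpx2 by 1.03. Wrn, a DNA helicase, Pth, parathyroid hormone, and Ube2s, a ubiquitin-conjugating enzyme of mitosis, were at least 4.49-fold, 3.91-fold and 3.78-fold higher. Wrn differed by 0.71 in the mean of its probe sets and Ube2s by 0.086 without probe sets marked as shared between transcripts, both short of 2-fold.

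Lower in the array labelled TET2 KD, apart from the genes above, was Ifrd1, at 9.64 and 7.22. Zmat3, a p53 target, read 9.68 and 7.36, and Dnajb11, a chaperone of the endoplasmic reticulum, 8.95 and 6.82. Cbr1, a carbonyl reductase, differed by -2.02 and the scaffold protein Iqgap2 by -2.01.

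Different probe sets of a gene often did not share these differences. Of 60 genes past 2-fold with another probe set at or above the floor, the others averaged 2-fold or more the same way in 9 (15%). Those 9 include Gh, Xist, Sec14l3, Serpinh1, Hspa1b and Hspb1, named after their values were seen. Gas7 differed by 2.51 in its brightest probe set and by 0.55 in the mean of all its probe sets. Where every one of 2 or more probe sets had to pass 2-fold, a rule added after the data were seen, 2 genes were higher and 7 lower.

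Heat shock proteins stood highest of the gene lists in the array labelled TET2 KD. Their median difference was 0.31, at percentile 100 of random lists, and 3 of 14 members were higher by 2-fold or more and none lower. These were Hspa1b, the small heat shock protein Hspb1 (1.34) and the heme oxygenase Hmox1 (1.10), while Hsph1 differed by 0.70. Hspb1 differed by 0.78 in the mean of all its probe sets, those under the floor included. Immediate early genes, which respond first to stimulation, had a median of 0.09 at percentile 98.3, with Fosb (2.07), Fos (1.42) and Klf10 (1.34) higher among 16. Without the members past 2-fold the immediate early median was 0.067, within the range of random lists.

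Cell cycle genes had a median of 0.05 at percentile 97.8, with 6 of 26 higher and none lower. The 6 were Top2a, a topoisomerase (2.30), Tpx2 (2.18), the cyclin Ccnb2 (1.76), the kinases Aurka (1.55) and Bub1 (1.32), and the centromere motor Cenpe (1.26). Top2a was under the floor in the array labelled control KD, at least 2.68-fold higher, and differed by 0.60 in the mean of its probe sets. Ccnb2 read 10.96 and 12.72 and differed by 0.74 after quantile normalization, which left Aurka at 0.997, so neither passed 2-fold. In the mean of their probe sets Bub1 (0.73) and Cenpe (0.68) were short of 2-fold as well. Without members past 2-fold the median turned to -0.040, within the random range. Those members were all higher, so leaving them out could only lower it. A second list of 58 proliferation genes had none past 2-fold at or above the floor. Differences there ran from -0.43 for Clspn to 0.91 for Spag5. Prc1, with a mean under the floor, read 1.21 and 2.84. Glycolysis and hypoxia genes had a median of 0.05 at percentile 99.1, with 0 of 27 past 2-fold. Slc2a1, a glucose transporter, was at 0.34 and Ero1a at -0.57, or -0.20 in the mean of its probe sets. The mean of members, 0.030, and the median against unmatched random lists or with 2 or more probe sets per gene lay within the random range.

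Ribosomal protein genes were slightly lower in the array labelled TET2 KD, with 45 of 49 below 0, a median of -0.05 at percentile 0.1, and none past 2-fold. Their mean, -0.053, and the median against unmatched random lists lay within the random range. Genes of the unfolded protein and ATF4 response had a median of -0.08 at percentile 1.57, and 6 of 26 were lower by 2-fold or more. They were the amino acid transporter subunit Slc3a2 (-2.32), Creld2 (-1.91), the disulfide isomerase Pdia4 (-1.67), Sdf2l1 (-1.46), the serine synthesis enzyme Psph (-1.32) and Atf5 (-1.16). Slc3a2 and Pdia4 were under the floor in the array labelled TET2 KD, at least 2.498-fold and 2.12-fold lower. Hspa5, the main chaperone of the endoplasmic reticulum, differed by 0.60, but by -0.38 in the mean of its probe sets. Beside the 6 lower, some members differed upward short of 2-fold, such as Manf (0.58), Xbp1 (0.37) and Dnajb9 (0.31). Hsp90b1 (0.36) and Herpud1 (0.17) did too, but differed by -0.45 and -0.84 in the mean of their probe sets. Without the members past 2-fold the median was -0.015, within the range of random lists.

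Of 30 lists with enough members, these 6 stood apart and 24 did not, where 1.5 would if members varied like randomly drawn genes. Lists whose members vary together would stand apart more often, so 6 beside 1.5 is no measure of an excess. The number standing apart was 3 without members past 2-fold, 3 against unmatched random lists and 2 of 20 with 2 or more probe sets per gene. Lists for H2B histones, for sex-linked genes and for transcripts of the earliest embryo had under 5 members at or above the floor and no median. The medians of the TET and DNA methylation genes (-0.05) and of the O-GlcNAc genes (0.03) lay within the range of random lists, and 0 of 18 and 0 of 16 members passed 2-fold. The methylation-linked gene Gadd45b differed by 0.90, and Sin3a, a partner of OGT, by -0.75, or -0.13 without probe sets marked as shared between transcripts. Pluripotency genes had a median of 0.00, with Klf4 (1.01, or 0.76 in the mean of its probe sets) the member past 2-fold of 21. Germline genes, many kept silent by DNA methylation, had 0 of 13 past 2-fold, with Dazl at 0.23. With the floor at the 75th percentile their median, of 6 members, was 0.13, above the random range. Sycp3, a meiotic protein, read 8.24 and 8.28, while 17 of 30 germline genes were under the floor on both arrays. Of 32 imprinted genes Dlk1 (-1.28) was past 2-fold.

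Lineage markers gave few large differences. In primitive endoderm Thbd, thrombomodulin, was higher at 3.21 and 4.21. The collagen chaperone Serpinh1, at 5.29 and 4.04, and the laminin Lama1 (-1.03) were lower among 22, and the median of -0.07 stayed within the range at percentile 4.99. With the floor at the 75th percentile that median was -0.16, below the range. Levels on both arrays were high for some genes outside the brain lists too. Ttr, transthyretin, of the primitive endoderm list read 10.60 and 10.73. Hba-a1, a hemoglobin chain, read 10.39 and 10.33, while 11 of 19 blood and endothelial genes were under the floor on both arrays. None of 10 mesendoderm, 18 neuroectoderm, 11 trophoblast, 14 primed epiblast, 6 Hox or 7 blood and endothelial genes at or above the floor passed 2-fold. Of 17 fibroblast genes the collagen cross-linker Lox (-1.17) did, at least 1.95-fold lower against the floor and -0.32 in the mean of its probe sets, and Fn1, fibronectin, differed by -0.90.

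Signalling and chromatin lists also lay within the range of random lists here. In alternatives, p53 targets (0.069 after quantile normalization), cholesterol genes (0.069 with the floor at the 25th percentile), the Nodal and activin pathway (0.15 with the floor at the 75th percentile) and interferon genes (0.13 in the mean of probe sets) stood above it. In the Wnt list Lgr5 (1.52) was higher and Znrf3 (-1.43) lower among 15, but at 0.72 and -0.65 both were short of 2-fold in the mean of their probe sets. Of 16 genes of the FGF pathway Spry1, a feedback inhibitor, was past 2-fold (1.37). The inhibitors Spred1 (-0.95) and Spred2 (-0.69) differed the other way, but by -0.020 and -0.17 in the mean of their probe sets. Id3, a BMP target, differed by 1.12 and the interferon-induced Gbp2 by 1.38, or 0.71 in the mean of its probe sets. Lgr5 and Id3 were under the floor in the array labelled control KD, at least 2.09-fold and 2.00-fold higher. None of 28 Polycomb and trithorax genes passed 2-fold, with Cbx2 at -0.84 (-0.36 in the mean of its probe sets) and Ezh2, the H3K27 methyltransferase, at -0.61. Of 26 p53 targets, Gtse1 (1.46) and Ckap2 (1.20) were higher and Zmat3 lower. Among 38 oxidative phosphorylation genes Ndufa8 (-1.76) was lower, among 14 reference genes Tfrc was (-1.57, or -0.55 in the mean of its probe sets), and among 19 cholesterol genes Nsdhl (1.16) was higher. Nsdhl was under the floor in the array labelled control KD, and its bound of at least 1.53-fold is short of 2-fold. None of 13 genes of the Nodal and activin pathway passed 2-fold. Among 14 histone genes other than H2B, H2ax (1.01) was higher and H4c8 (-1.38) lower.

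**Figure D3:**
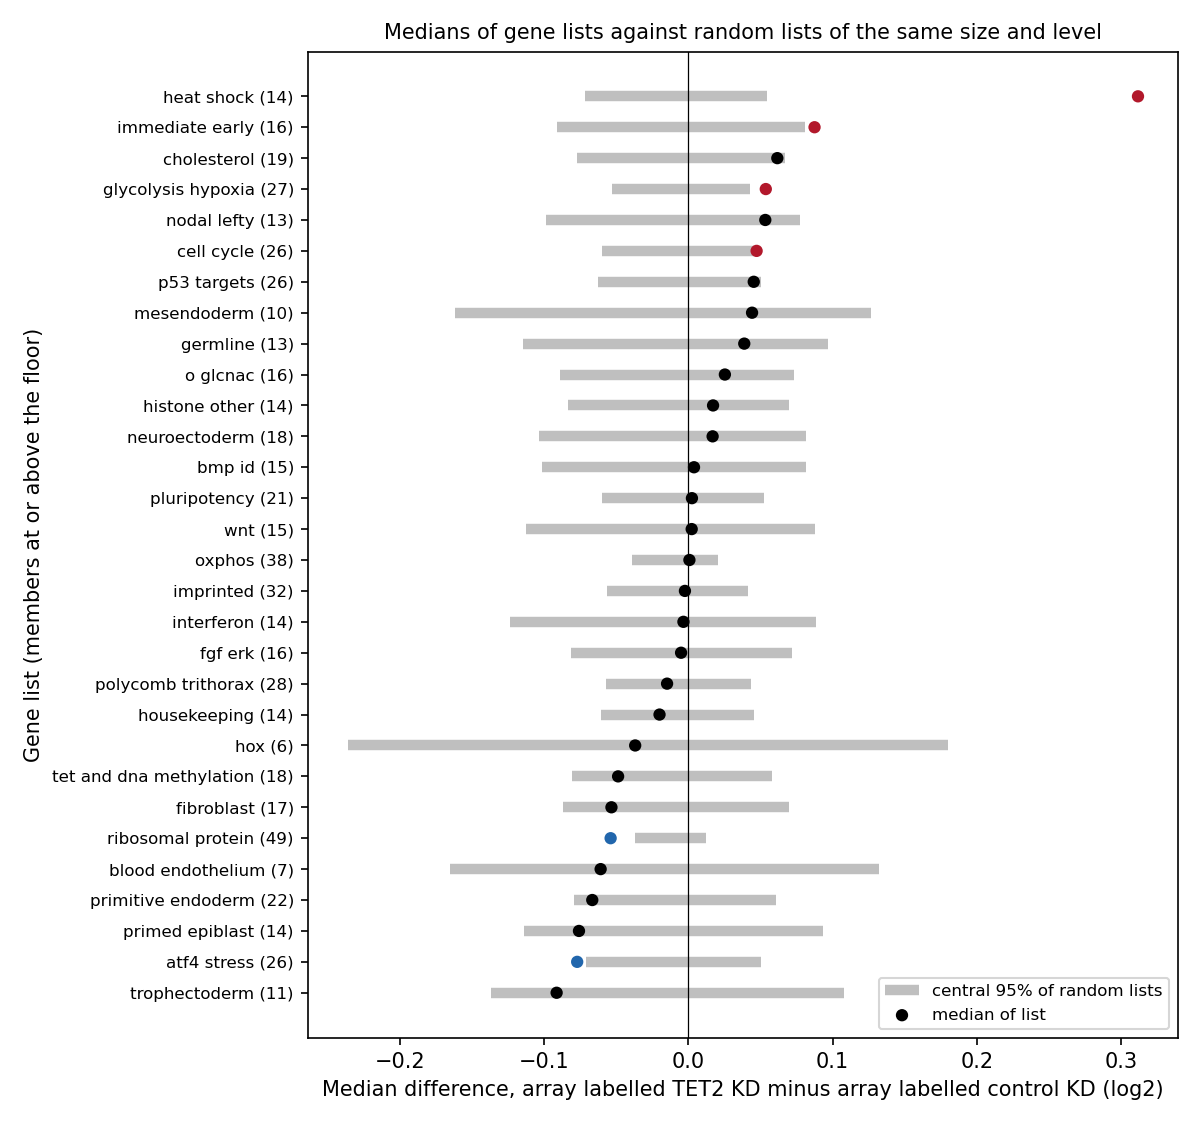
Median difference of each of 30 gene lists (points, array labelled TET2 KD minus array labelled control KD, log2, horizontal axis) beside the central 95% of random lists of the same size and level (grey bars), with the number of members after each name. Heat shock proteins, at 0.31, lie farthest from their bar, and ribosomal protein genes, at -0.05, lie below theirs.

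The bioC hybridization spikes averaged 5.83 in the array labelled control KD and 5.76 in the array labelled TET2 KD, bioD 8.14 and 8.08, and cre 9.92 and 9.84. The 3' probe set exceeded the 5' probe set by 1.23 and 1.11 for beta-actin and by 0.40 and 0.27 for Gapdh, a measure of RNA integrity and labelling, and by 0.53 and 0.73 for 18S rRNA.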

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

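Probe sets with no gene name, or with several, entered no comparison above. At or above the floor there were 6020 of them, and 46 were higher by 2-fold or more in the array labelled TET2 KD and 49 lower. They are listed because a signal stood above the control array in data that the gene counts leave out, and no explanation was tested. Whether any of them belong to genes named above, or to genes without a probe set such as the Y-linked Ddx3y, was not checked. The 3 largest differences upward among probe sets without a name were 4.31 for 1426439_PM_at, 4.24 for 1452077_PM_at and 4.13 for 1430234_PM_at, each from 1 array per group.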

How the results depend on the processing

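The rule that every one of 2 or more probe sets must pass, and those on equal values and values set to the floor, were added after seeing the data. Averaging all probe sets of a gene was planned. No paired analysis was possible because each group has 1 array, and for the same reason no array could be left out. The planned pseudocounts were not run because the values are already on a log scale. Under every scaling run, both Tet2 differences stayed negative and short of 2-fold, and every scaling left both counts within 1.5 times. A floor cannot change the difference of a single probe set. Raising the floor to the 75th percentile gave 80 genes higher and 60 lower, fewer genes being compared. Averaging all probe sets of a gene gave 87 higher, and 188 genes were past 2-fold under both that rule and the main one, of 193 and 289. A threshold of 1.5-fold gave 199 and 606, and 3-fold gave 55 and 61. Asking every one of 2 or more probe sets to pass gave 2 and 7. Leaving out probe sets with both values equal to another's gave 131 and 158, the same as the main rule. Probe sets equal to another on 1 array alone stayed in. Hmgb3 and Herpud1, for example, both read 6.19016 in the array labelled control KD. Setting values under the floor to it gave 128 and 142. Lists standing apart numbered 3 without members past 2-fold, 3 against unmatched random lists and 2 with 2 or more probe sets, where 20 lists could be read. Heat shock proteins stood apart in every list alternative run. The cell cycle median no longer stood apart after quantile normalization (0.054) and with the floor at the 25th percentile (0.012). The same held with no floor (0.011) and against unmatched lists (0.047). Its sign turned without members past 2-fold (-0.040) and with 2 or more probe sets (-0.109), both within the random range. The members past 2-fold were all higher, so leaving them out could only lower the median. The ATF4 median fell within the random range at the 75th percentile floor (-0.0065), the floor from receptor genes (-0.070), without members past 2-fold (-0.015) and with 2 or more probe sets (-0.102). The immediate early median did so at the 75th percentile floor (0.071) and without members past 2-fold (0.067). Glycolysis did so by the mean of members (0.030), against unmatched lists (0.054) and with 2 or more probe sets (0.046), and ribosomal proteins by the mean of members (-0.053) and against unmatched lists (-0.054). Of the lists within the range here, 6 stood apart in some alternative, among them primitive endoderm (-0.16) and the Nodal and activin pathway (0.15) with the floor at the 75th percentile. The cause was not tested for any of these lists. Of 158 named genes, 19 moved by over 1.5-fold in some alternative, such as Wrn to 0.71 in the mean of its probe sets and Ube2s to 0.086 without probe sets marked as shared between transcripts. The sign differed in some alternative for 6, of which 0 were past 2-fold here. Genes near the floor of 2.55 are limited by signal over background.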

Other observations

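Differences downward were more frequent than upward just short of 2-fold. Between 0.6 and 0.7 on the log2 scale, 22 genes were higher in the array labelled TET2 KD and 146 lower, and between 0.9 and 1.0 the numbers were 12 and 70. Between 1.0 and 1.1 they were 22 and 28. In a second list of 58 proliferation genes, none at or above the floor was past 2-fold, with differences from -0.43 to 0.91. Among members picked after their values were seen, Mad2l1, a spindle checkpoint protein, read 9.91 and 10.08, Smc4, a condensin subunit, 9.38 and 9.40, and Anln, a cytokinesis protein, 9.27 and 9.18. The kinesin Kif22 read 1.67 and 1.72, under the floor.

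Tests of the shift of probe set names, of the sex-linked genes and of several probe sets per gene were chosen after their results, or values that bear on them, had been seen. Tests on the second lists were written before the values of those members were looked at, although cell cycle genes had been seen to lie both above and under the floor. The limits of 20, 25 and 80% were chosen without a reference distribution. For the levels of ES cell and brain genes, earlier tests on lists already seen (92.3% of oligodendrocyte genes and 61.8% of pluripotency genes at or above the floor on both arrays) were replaced by the second proliferation list after both had argued against what they tested, ES cells alone and a mixture. The readings of the second lists and of dim probe sets were made more cautious after the results were known, when the rule for the sex-linked genes was also changed and base shares among all genes were added.

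Some ES cell genes and some brain genes were high, with Pou5f1 and Nanog at background. A shift of all probe set names by 1 place was tested in 1 direction alone. The correlation across genes between 2 probe sets of a gene was 0.290 as deposited and 0.125 after moving the values by 1 row. That argues against a displacement which this move would undo. It says nothing of a shift the other way, 0.290 is low, and a partial misplacement stays open as well. A mixture of ES cell and brain RNA would bring all abundant transcripts of dividing cells, and 67.2% of the second proliferation list was at or above the floor on both arrays, under the 80% set beforehand, but that limit left no room for probe sets that fail, and the share among all genes was 63.96%. Values from more than 1 RNA source side by side in the table may be a candidate explanation, with 29.3% of that list under the floor on both arrays and 53.4% at or above the 75th percentile, although 33.4% of all genes were under the floor too. A mixture, several sources and failed probe sets cannot be told apart with these shares.

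Xist, 2 Y-linked genes, and pituitary and epithelial genes separated the arrays, and a difference from the knockdown itself was not tested, since Tet2 does not separate them. A single cell line on both arrays is argued against, where values and names are aligned, since the mean Xist difference was -5.68, or -5.004 with values under the floor set to it, and Eif2s3y and Kdm5d were at least 12.0-fold and 3.91-fold higher in the array labelled TET2 KD. Loss of a chromosome in culture would bring neither Y-linked RNA to a female line nor Xist to a male one, and Sry, at 3.04 and 2.84 and close to the floor, did not differ. Pituitary tissue and olfactory and airway tissue in the array labelled control KD cannot be told apart from other sources. The second pituitary list had a median of -0.040, within its random range from -0.097. The second olfactory and airway list had -0.11, below its range from -0.088 (percentile 0.74), so it met the prediction written beforehand and the pituitary list did not. But 9 of 14 and 11 of 19 members were under the floor on both arrays. Scgb1a1, an abundant airway protein, was among them at 1.24 and 1.12, so the limits written for both were wrong. Members at or above the floor on both arrays were read apart only afterwards. Of these, 2 of 4 pituitary genes were below 0, with Cpe at 0.0045 and Chga at -0.12. The same held for 5 of 6 olfactory and airway genes, and none passed 2-fold. That filter leaves out genes absent from 1 array. Of all 19 olfactory and airway members 2 were lower by 2-fold and 0 higher. These were Cnga4 (2.71 and 1.28) and Ugt2a1, under the floor on both arrays (2.34 and 0.94). Of 14 pituitary members 0 were lower by 2-fold and 1 higher.

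Large differences were mostly seen in 1 probe set of a gene: in 15% of 60 genes the others moved 2-fold or more the same way. A test for a change of the whole transcript was dropped, since it restated that share. Noise of dim probe sets cannot be told apart from other sources by these levels. Of the 51 genes that disagreed, 31.4% had both arrays in the upper 50% of levels, against 66.1% of all genes with several probe sets. The 51 were picked for a large difference (median 1.37), which puts their lower array well under their mean. Part of that gap is therefore built in, and the limit of 25% ignored the base share. Of these genes, 9.80% had a brightest probe set whose name marks a cross-hybridising design. The share among all genes with several probe sets was 18.01%, so such names were not in excess among the brightest probe sets. The names of the other probe sets were not read, so cross-hybridisation there stays open. What sets these probe sets apart stays open, and no biological explanation was tested.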
